A study of Oryza sativa with 35 samples.

How the data were processed

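Gene expression was measured on the Affymetrix Rice Genome Array, a 1-colour array on which each transcript is read by a probe set, in 35 samples of rice (Oryza sativa cultivar Nipponbare) at heading. One table of values was used, which holds 57381 probe sets for each of the 35 arrays. The deposited values are signal intensity on a linear scale: they run from 0.0536 to 66643, and the trimmed mean of each array lies between 500.06 and 500.08, so the authors' deposited intensities carry a common trimmed mean, as the values show. The software of that summary and scaling is not given in the sources used here. Samples were grouped by the labels, which name organ and part and number the biological replicates; 0 value columns were left without a sample.

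Values were set to a floor of 1 and taken to log2. The groups, the comparisons of organs with their tests and the choice of scaling by the array medians were set before the data were examined; tests of explanations chosen later are named in the closing part. The array medians (5.39 to 6.36, a gap over 0.5) led to quantile normalization over all 35 arrays. The 123 control probe sets were left out, and of the 57258 others the 38647 at or above the median of all values (5.83) on at least 3 of the 32 replicated arrays were tested. A linear model with 1 mean per group was fitted to these arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (21 residual degrees of freedom, prior degrees of freedom 1.65). All groups share 1 estimate of the spread of each probe set. Adjusted p-values are Benjamini-Hochberg values over all probe sets tested, within a comparison. A probe set was called at an adjusted p under 0.05 with a change of at least 2-fold. Errors are limma's standard errors with the moderated spread, and 95% intervals use the same spread. The 3 whole-blade arrays without replicates were normalized with the rest and kept out of the fit and of every test.

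Probe sets were named from the annotation of the array's platform, which lists 22531 probe sets, 22436 with 1 gene and 95 with several, and symbols were updated through the gene number in a table of rice genes. Of the probe sets tested, 20915 have 1 gene, 85 several and 17647 are not listed there and are unnamed here. No gene was named from a probe set with several genes, and no coordinates are given, since the genome build behind the platform annotation is not given in the sources used here. Levels of a gene with several probe sets are those of the one with the highest mean, which was also used in list tests; the genes with the largest changes were taken at the probe set that showed them, and 2465 genes have a name other than a locus or clone identifier.

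Gene lists were tested with camera of limma at a preset correlation of 0.01 between members, adjusted over the lists within a comparison, and again with an estimated correlation. Lists with under 4 measured members were not tested. The 19 lists fixed beforehand held 241 genes by locus. The reference tables carry no such locus names, so members were matched by symbol and chromosome: 137 were matched, 89 had no symbol match, 11 had no probe set and 4 had several matches. Planned lists built from words of gene descriptions could not be built from these tables, and 43 lists built from patterns of gene symbols took their place. These patterns were written with the reference tables in hand and before any expression value of their members was seen. Membership in them rests on symbols alone, so the name of a list may not hold for every member. Counts "adjusted over the list alone" are given for the lists fixed beforehand. The lists overlap: some genes of chlorophyll synthesis are also in the list of the photosynthetic apparatus, and PCNA and MCM genes are in more than 1 list of cell division. Of 440 list tests 73 were called and 2 held with an estimated correlation.

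The rule for the genes named was also fixed beforehand. It takes, for each comparison, the 5 called probe sets with the largest rise and the 5 with the largest fall that have 1 named gene and a level at or above the 75th percentile in the higher group. From each list it takes up to 4 called members with the largest change, and any member that a sentence on its list needs. A few genes were named in advance for single comparisons; among them SPDT and NAP were not matched and are not analysed here. The same conditions gave the 5 organ-preferring genes of largest margin and the whole-blade genes. The reference tables have no gene descriptions, so the condition on descriptions became a condition on having a name. Genes singled out in the closing part for opposite changes were chosen after their values were seen.

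The steps were tested on simulated arrays drawn from the means and SDs of the 38647 probe sets, with known changes in a random set of them. For nodes against internode I, 89 of 100 changes of 3 log2 units and 62 of 100 of 1.5 were recovered with 7 false calls, and for flag sheath base against top 74 and 44 with 2. All simulated groups had the same SD of a probe set, while the real median SD was 0.468 at the sheath base and 0.235 at its top. The simulation does not cover that larger spread. For the organ-preferring rule 120 of 200 raised probe sets were recovered with 0 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

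Alternatives tried were the deposited scale, array medians set equal, log2(signal + 16) in place of the floor, no filter or one at the 75th percentile, a trend in the prior variance, leaving out probe sets whose names mark possible cross-hybridization, array weights, the replicate number as a block, a fit of the compared arrays alone and leaving out each array in turn. For gene lists, an estimated correlation and the mean of all probe sets of a gene were tried. Chosen after seeing the data were a scaling that sets the means of 27 hybridization control probe sets equal, tried because these controls lie at 11.11 on the 17 leaf arrays and 11.62 on the 18 others, leaving out both flag sheath base arrays, and the settings given for genes with opposite changes in the closing part. The difference between 3' and 5' actin probe sets, a measure of RNA integrity, ran from 0.89 in flower to 1.97 at the blade base (log2 group means).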

Results

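Gene expression in organs of rice (Oryza sativa, cultivar Nipponbare) at heading was measured on 35 1-colour Affymetrix arrays that fall into 14 groups. The flower before anthesis, the panicle branch, the top and the base of internode I, node I, node II, the tip, middle and base of the flag leaf blade and the top of the flag leaf sheath had 3 arrays each. The base of the flag leaf sheath had 2 arrays, and the whole blades of the flag leaf, leaf 2 and leaf 4 had 1 array each. The labels call the repeats biological replicates without saying whether they came from separate plants, so the p-values measure the spread between these samples. Of 57258 rice probe sets, 38647 were bright enough to be tested, and the small number of arrays per group limits the precision of each value. Replicate arrays correlated across probe sets at r = 0.917 to 0.951 in the groups of 3, and the 2 sheath base arrays at r = 0.864; probe sets are not independent replicates. Differences are given in log2 ± SE from limma, a probe set was called at an adjusted p under 0.05 with a change of at least 2-fold, and rose, fell, higher and lower refer to such calls unless a value is said not to pass. Where a compared mean lies below 5.83, the median of all values, the size of a difference depends on how low signals are treated. For folds against such means the difference on log2(signal + 16) is also given.

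Nodes are the joints of the stem, where the vascular bundles of stem and leaf meet. They were compared with internode I (6 node arrays, 6 internode arrays), and the largest named rises included transporters of mineral elements. ZIP3, of the zinc and iron transporter family, was 725-fold higher in the nodes (log2 9.50 ± 0.34, adjusted p = 2.2e-15), with all 6 node arrays above every internode array. Lsi2, a silicon efflux transporter, was 573-fold higher (9.16 ± 0.66, adjusted p = 1.2e-10), and the silicon transporter Lsi6 8.33-fold (3.06 ± 0.27, adjusted p = 2.96e-09). Genes of photosynthesis were lower in the nodes, among them the small subunit of Rubisco, RBCS (-3.97 ± 0.15, adjusted p = 2.2e-15).

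Of 26 mineral element transporters measured, 11 rose and 5 fell (11 and 5 adjusted over the list alone). Beside ZIP3, Lsi2 and Lsi6, the vacuolar iron transporter VIT2 (4.19 ± 0.50) rose, and so did the sodium transporter HKT1;5 (3.31 ± 0.40). The heavy metal transporter HMA2 was higher by 1.09 ± 0.35 (adjusted p = 0.0145), and by 0.99 without node I replicate 3 and 0.93 without node II replicate 1, under the 2-fold limit, while YSL16 differed by 0.73 ± 0.23, under the 2-fold limit (adjusted p = 0.0134). The internode value averages top and base, so a difference from the nodes can come mostly from a single part. HMA2 read 9.28 to 10.53 on the node arrays, 9.02 to 9.30 at the internode top and 8.29 to 8.56 at its base. The list as a whole was not called against all genes (adjusted p = 0.357). Among 20 genes of ammonium and nitrate uptake and assimilation, 5 rose and 2 fell: the ammonium transporter AMT1-3 was 116-fold higher (6.86 ± 0.23), and the chloroplast glutamine synthetase GLN2 was 24.1-fold lower (-4.59 ± 0.14). The gene printed as AMT1-3 is also listed under the name AMT1-2, so which member of the family it is stays open here and below.

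WOX11, a homeobox gene of crown root growth, was 121-fold higher (6.92 ± 0.75). Of 9 GH3 auxin-conjugating enzymes, 6 rose, with GH3.1 at 5.81 ± 0.71 and GH3.4 at 5.72 ± 0.61. Of 25 expansins, which loosen cell walls, 10 rose and 0 fell, with EXPA1 at 4.89 ± 0.86 and EXPA6 at 4.81 ± 0.35. Of 6 KNOX homeobox genes 4 rose (OSH6 3.69 ± 0.50, OSH71 2.49 ± 0.57). The dehydrin gene RAB16A was higher by 1 probe set (9.65 ± 0.89) and by the brighter one used for lists (6.05 ± 0.56). A list of DNA replication genes, which holds licensing and origin recognition factors and others such as RFC4, shifted up. Of its 23 members 8 rose, such as MCM4 (3.13 ± 0.62, and 1.51 on log2(signal + 16)) and RFC4 (2.20 ± 0.12), with adjusted p = 0.0266, and adjusted p = 0.543 with an estimated correlation.

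Of 23 nuclear genes of the photosynthetic apparatus, 19 fell and 0 rose (LFNR1 -3.84 ± 0.16, PSB28 -3.06 ± 0.16); the list test gave adjusted p = 2.18e-16, and adjusted p = 0.159 with an estimated correlation. Of 8 chlorophyll synthesis genes 6 fell (6 adjusted over the list alone), including CHLI (-2.99 ± 0.61, and -1.86 on log2(signal + 16)) and CHLH (-2.69 ± 0.15), with adjusted p = 3.1e-05, and adjusted p = 0.159 with an estimated correlation. The (p)ppGpp synthase CRSH2 fell by 5.76, the glycine decarboxylase subunit GDCSH dropped by 5.24, and the aquaporin PIP2-7 decreased by 4.43 on the log2 scale. The peroxiredoxin PRXIIE-2 differed by -4.76 ± 0.28 (adjusted p = 4.8e-12; -4.38 on log2(signal + 16)). A list built from symbols of cytosolic ribosomal proteins went the other way, 10 of 21 higher and 2 lower (adjusted p = 3.18e-05, and adjusted p = 0.543 with an estimated correlation). RPL7A was at 2.01 ± 0.11 and RPL18 at -3.25 ± 0.15. Whether each member, RPL18 among them, is cytosolic and not of the chloroplast was not checked.

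By limma's test 4429 probe sets were higher and 4164 lower in the nodes (9488 and 7381 without the 2-fold limit), with a median of 0.03 over all probe sets tested. With the hybridization controls set equal that median was 0.22, and 5763 were higher and 3120 lower. On log2(signal + 16), ZIP3 rose by 8.06, Lsi2 by 7.68, AMT1-3 by 4.76 and WOX11 by 5.32.

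**Figure D1:**
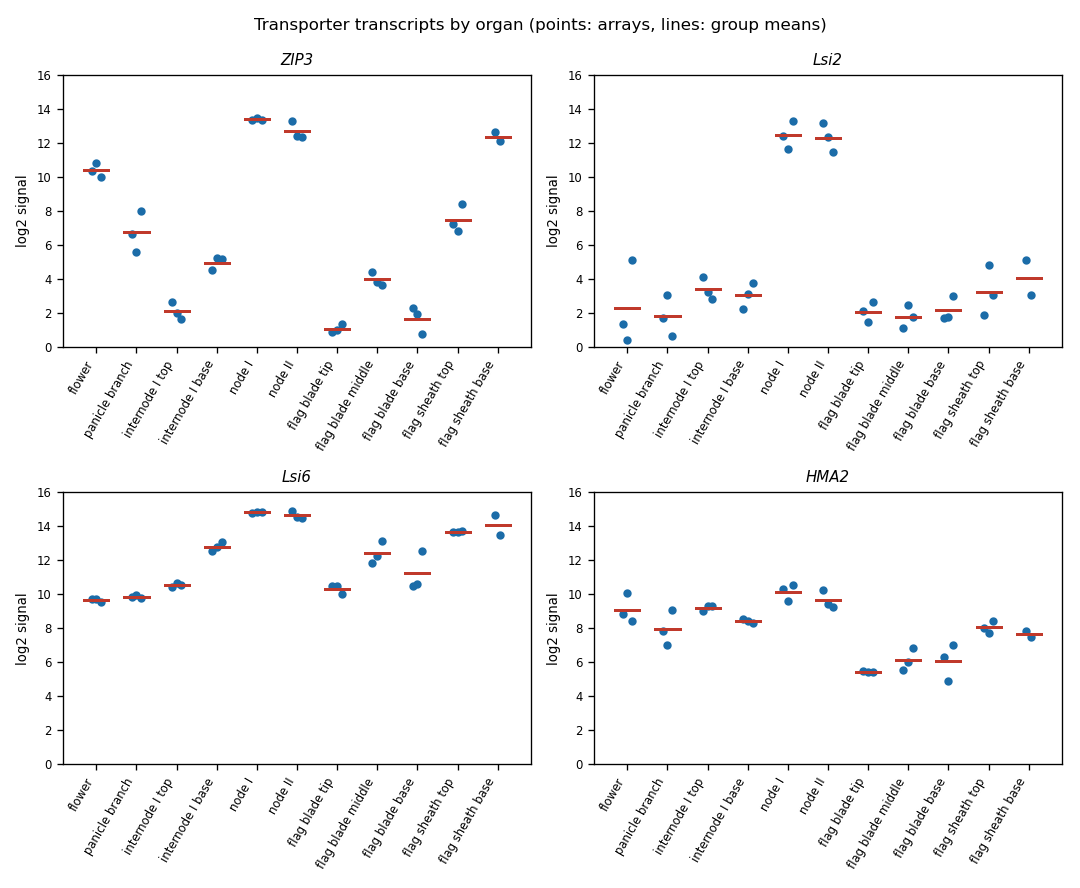
Log2 level of ZIP3, Lsi2, Lsi6 and HMA2 on each array of the 11 replicated groups after quantile normalization; points are arrays and short lines are group means. ZIP3 is at a mean of 13.02 in the nodes and 3.52 in internode I, and Lsi6 at 14.74 and 11.68. The flag sheath base arrays read 12.62 and 12.08 for ZIP3 and 14.67 and 13.48 for Lsi6, so high levels are not confined to the nodes.

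Node II and node I, compared with 3 arrays each, differed at few probe sets. Node II had 3.77-fold more transcript of the chitinase Cht11 (1.91 ± 0.40, adjusted p = 0.0452), and less of MADS34 (-2.80 ± 0.49, adjusted p = 0.0158), of the auxin-conjugating enzyme GH3.11 (-2.78 ± 0.54, adjusted p = 0.0265) and of the light-harvesting protein LHCB3 (-1.26 ± 0.23, adjusted p = 0.0179). ERH1 was lower by -1.12 ± 0.18, and the kinesin KIN14R (2.46 ± 0.52) and the replication protein RPA32A (2.14 ± 0.42) were higher. Genes of cell division shifted up as lists in node II although few members were called. The list tests were not repeated with an array left out or on the 6 node arrays alone, so how far they rest on single arrays is not known. Of the 23 members of the list of DNA replication genes 1 rose (list test adjusted p = 6.89e-06, and adjusted p = 0.048 with an estimated correlation). Of 8 mitotic cyclins and B-type cyclin-dependent kinases limma called 0 higher, and 6 were higher at an unadjusted p under 0.05 (list test adjusted p = 1.85e-05, and adjusted p = 0.048 with an estimated correlation). The kinesins (adjusted p = 2.09e-05, and adjusted p = 0.088 with an estimated correlation) shifted up and the photosynthetic genes shifted down (adjusted p = 9.4e-07, and adjusted p = 0.396 with an estimated correlation). The transporters Lsi6 (-0.19 ± 0.38, 95% interval -0.98 to 0.59), HMA2 (-0.49 ± 0.50, -1.52 to 0.53) and YSL16 (0.37 ± 0.33, -0.31 to 1.04) did not pass.

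In total 28 probe sets were higher and 48 lower in node II, without the 2-fold limit 33 and 59, and 3379 had an unadjusted p under 0.05. The median of all probe sets was -0.01, and -0.18 with array medians set equal. On the deposited scale 49 were higher and 34 lower, and in a fit of the 6 node arrays alone 0 and 0 by limma, with 4348 at an unadjusted p under 0.05 in that fit. The higher count was 47 without node I replicate 2, 15 without node I replicate 3, and 51, 10 and 14 without node II replicate 1, 2 and 3. The lower count was 13 and 14 without node I replicate 1 and 3. Each gene named as higher or lower here lost its call without at least 1 array. Without node I replicate 1 these were Cht11 (adjusted p = 0.0541), MADS34 (adjusted p = 0.0658), GH3.11 (adjusted p = 0.15), LHCB3 (adjusted p = 0.0687), ERH1 (adjusted p = 0.0541) and RPA32A (adjusted p = 0.0661). Without node I replicate 2 these were Cht11 (adjusted p = 0.0995), LHCB3 (adjusted p = 0.0522) and KIN14R (adjusted p = 0.168). Without node I replicate 3 these were Cht11 (adjusted p = 0.181), MADS34 (adjusted p = 0.0545), GH3.11 (adjusted p = 0.102), LHCB3 (adjusted p = 0.0545), KIN14R (adjusted p = 0.126) and RPA32A (adjusted p = 0.128). Without node II replicate 1 these were Cht11 (adjusted p = 0.143), GH3.11 (adjusted p = 0.0616) and LHCB3 (adjusted p = 0.0637). Without node II replicate 2 these were LHCB3 (adjusted p = 0.0587), KIN14R (adjusted p = 0.175) and RPA32A (adjusted p = 0.0585). Without node II replicate 3 these were Cht11 (adjusted p = 0.122), GH3.11 (adjusted p = 0.122), KIN14R (adjusted p = 0.174) and RPA32A (adjusted p = 0.128). The call of Cht11 was also lost on the deposited scale (adjusted p = 0.0614), with array medians set equal (0.109), with no filter (0.0733), without probe sets marked for possible cross-hybridization (0.0509) and with the hybridization controls set equal (0.0852). Setting these controls equal also ended the calls of GH3.11 (adjusted p = 0.0679) and ERH1 (0.105), and KIN14R lost its call with no filter (0.0801) and without the marked probe sets (0.0516). None of the 7 was called in the fit of the 6 arrays alone.

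Internode I differed along its length more than any other pair compared, by the number of probe sets called. At its base (3 arrays, against 3 of the top) genes that build cell walls were higher. The secondary wall cellulose synthases CESA9, CESA4 and CESA7 were 99.3-fold, 66.1-fold and 46.2-fold higher (6.63 ± 0.80, 6.05 ± 0.68 and 5.53 ± 0.75; adjusted p = 4e-07, 1.33e-07 and 1.83e-06), with all 3 base arrays above every top array for each. The top was higher in genes of the chloroplast and in Hd3a, a florigen gene, which was 595-fold lower at the base (-9.22 ± 0.66, adjusted p = 1.38e-10).

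All 6 measured genes of secondary wall cellulose and lignin synthesis rose (6 adjusted over the list alone), with BC1 at 5.59 ± 0.67; the list test gave adjusted p = 0.00235, and adjusted p = 0.102 with an estimated correlation. All 5 primary wall cellulose synthases rose too (5 adjusted over the list alone), led by CESA5 (5.05 ± 0.67) and CESA6 (4.20 ± 0.50), with adjusted p = 0.00222, and adjusted p = 0.336 with an estimated correlation. Of 15 xylan synthesis and acetylation proteins 12 rose, XOAT14 by 7.13 ± 0.83 and XOAT6 by 4.84 ± 0.33 (adjusted p = 1.43e-06, and adjusted p = 0.193 with an estimated correlation). The laccase LAC3, an enzyme of lignin polymerization, was 446-fold higher (8.80 ± 0.92), LAC10 rose by 7.32 ± 0.50, and LAC7 fell by 5.80. Of 22 CASP-like membrane proteins 11 rose and 1 fell, with OsCASPL1B1 824-fold higher (9.69 ± 1.18) and the list at adjusted p = 0.00222, and adjusted p = 0.193 with an estimated correlation. A peroxidase gene (LOC4339222) rose by 9.40 ± 1.35, the zinc finger gene OsC3H9 by 8.91 ± 1.16 and the ABC transporter gene RCN1 by 8.19 ± 1.13.

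Motor and cytoskeleton genes were raised at the internode base: of 32 kinesins 17 rose and 5 fell (KIN14B 6.75 ± 0.94, KIN5A 5.32 ± 0.73; adjusted p = 0.00222, and adjusted p = 0.285 with an estimated correlation), and of 9 beta and gamma tubulins 6 rose (TUBB4 4.36 ± 0.42; adjusted p = 0.0075, and adjusted p = 0.493 with an estimated correlation). Sucrose synthase SUS1 rose by 6.51 ± 0.93. Of 6 genes in the cell division list 5 fell (5 adjusted over the list alone; PCNA -3.18 ± 0.32, CYCB2;2 -3.89 ± 0.97), though the list test did not pass (adjusted p = 0.147), and the cyclin CYCB1-1 fell by 6.05. CYCB1-1 had a mean of 1.27 at the base, and on log2(signal + 16) it fell by 3.24 and CYCB2;2 by 1.46. Of 21 cytosolic ribosomal proteins 17 fell (RPL9 -2.32 ± 0.15; adjusted p = 9.21e-08, and adjusted p = 0.336 with an estimated correlation).

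Photosynthetic transcripts were lower at the internode base, with 16 of 23 nuclear genes down (RBCS -6.36 ± 0.21, ndhM -3.97 ± 0.25; adjusted p = 6.86e-06, and adjusted p = 0.493 with an estimated correlation). The chloroplast aldolase ALDP fell by 9.82, the sugar transporter SWEET1B dropped by 7.67, ASMT3 decreased by 7.74 and PHR3 fell by 7.10. Of 8 genes in the chlorophyll synthesis list 6 fell (6 adjusted over the list alone, adjusted p = 0.0158, and adjusted p = 0.377 with an estimated correlation), among them the transcription factor GLK1 (-2.94 ± 0.28). The gibberellin genes EUI1 (-1.76 ± 0.85, adjusted p = 0.096) and GA20ox2 (-0.40 ± 0.43, adjusted p = 0.48) did not pass, although EUI1 did without top replicate 3 (-2.59, adjusted p = 0.022) and without base replicate 2 (-2.78, adjusted p = 0.0102), while without base replicate 3 it differed by -0.95. Limma called 5352 probe sets higher and 7212 lower at the base (7572 and 10499 without the 2-fold limit). The median of all probe sets was -0.12, and -0.26 with the hybridization controls set equal, so the ribosomal decrease (median -1.38) exceeded that shift. On log2(signal + 16) OsCASPL1B1 rose by 7.80 and LAC3 by 7.04, Hd3a fell by 7.67 and ALDP fell by 7.71.

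The flag leaf blade changed little from tip to base (3 arrays each). At the base BURP17 was 133-fold higher (7.06 ± 0.98, adjusted p = 0.000624; 5.28 on log2(signal + 16)), and the metallothionein MT2C 9.11-fold (3.19 ± 0.55, adjusted p = 0.00452). The MADS-box genes MADS34 (2.83 ± 0.49) and MADS15 (2.56 ± 0.38) and the protochlorophyllide reductase PORA (1.96 ± 0.33) were also higher. The tip was higher in the alternative oxidase AOX1 (base minus tip -2.41 ± 0.32, adjusted p = 0.000488), CYP71P1 (-2.39 ± 0.45), the phytosulfokine precursor PSK5 (-2.16 ± 0.43), BZIP60 (-1.67 ± 0.31) and ABCG36 (-1.64 ± 0.28). In the middle of the blade BURP17 had a mean of 12.76, against 2.68 at the tip and 9.74 at the base, and AOX1 one of 9.05, against 11.75 and 9.35. These differences from the middle were not tested. Without tip replicate 1 CYP71P1 differed by -1.54 and was still called.

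Of 17 floral MADS-box regulators 2 rose (2 adjusted over the list alone), both named above, with adjusted p = 0.0352, and adjusted p = 0.46 with an estimated correlation. Aux/IAA repressors shifted up as a list, although limma called 0 of 24, with 11 higher at an unadjusted p under 0.05 (adjusted p = 4.46e-05, and adjusted p = 0.46 with an estimated correlation). Of 8 dehydration and heat response genes 1 fell (1 adjusted over the list alone), LEA3 by 5.62, with adjusted p = 0.0399, and adjusted p = 0.475 with an estimated correlation. With array medians set equal the list had an adjusted p of 0.11. Of 23 photosynthetic genes only PORA was called (list adjusted p = 0.67), and the chlorophyll breakdown gene SGR did not pass (-1.17 ± 0.46, adjusted p = 0.369). By limma 72 probe sets were higher and 109 lower at the base (77 and 122 without the 2-fold limit), with 3646 at an unadjusted p under 0.05. A fit of these 6 arrays alone called 0 and 2 (3227 at an unadjusted p under 0.05), and none of the 11 genes named. With the hybridization controls set equal, under which the median of all probe sets moved from 0.00 to -0.20, the counts were 37 and 154. Without tip replicate 1 the higher count was 116, without base replicate 3 it was 26, and without base replicate 2 the lower count was 69. Calls were lost for CYP71P1 (adjusted p = 0.067), PSK5 (adjusted p = 0.0825) and LEA3 (adjusted p = 0.0703) without base replicate 2, PSK5 (adjusted p = 0.07) without tip replicate 2 and LEA3 (adjusted p = 0.0709) without tip replicate 3.

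The base of the flag leaf sheath (2 arrays) was higher than its top (3 arrays) in genes of the cell wall and the cytoskeleton. CESA7 was 102-fold higher (6.67 ± 0.84, adjusted p = 4.37e-06), and CESA9 34.6-fold (5.11 ± 0.90, adjusted p = 0.000184). All 9 beta and gamma tubulins rose (TUBB1 5.11 ± 0.33, TUBB8 4.87 ± 0.59; adjusted p = 4.59e-06, and adjusted p = 0.208 with an estimated correlation). The top was higher in genes of phytoalexin synthesis and of the chloroplast: the copalyl diphosphate synthase CPS2 was 93.6-fold lower at the base (-6.55 ± 0.78, adjusted p = 2.62e-06), and the aldolase ALDP 72.1-fold (-6.17 ± 1.01). The 2 base arrays correlated at r = 0.864, the lowest of any replicate pair, and the means at the sheath base rest on these 2 arrays. Actin 3' minus 5', a sign of RNA quality, was 1.98 in base replicate 1 and 1.12 in replicate 2, and the mean of the hybridization controls 11.12 and 10.59. The same measure on ubiquitin was -0.67 and -0.58, and the 3' actin probe set itself read 12.44 and 14.36 on the deposited scale. On log2(signal + 16) CESA7 rose by 5.67 and CESA9 by 3.85, while CPS2 fell by 5.85 and ALDP by 5.63. Without base replicate 2 TUBB8 was higher by 3.08, still a call.

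Of 6 genes of secondary wall cellulose and lignin synthesis 5 rose (6 adjusted over the list alone; CESA4 4.17 ± 0.76; adjusted p = 0.00138, and adjusted p = 0.0737 with an estimated correlation), and all 5 primary wall cellulose synthases rose (5 adjusted over the list alone; CESA6 2.94 ± 0.56; adjusted p = 0.000614, and adjusted p = 0.326 with an estimated correlation). Of 15 xylan proteins 11 rose (XOAT11 4.38 ± 0.44; adjusted p = 0.000136, and adjusted p = 0.336 with an estimated correlation), and of 32 kinesins 20 rose (KIN14F 4.28 ± 1.29, KIN14B 4.28 ± 1.06; adjusted p = 0.000119, and adjusted p = 0.208 with an estimated correlation). The lipid transfer protein LTP110-B (7.91 ± 1.53), the beta-glucosidase BGLU30 (7.75 ± 1.54), the peroxidase gene LOC4339222 (7.67 ± 1.51) and FOR1 (6.14 ± 1.47) were among the largest rises, but replicate 2 of the base decided their size. Without it they differed by 3.65, 3.51, 3.95 and 1.52, KIN14F by 1.88, RPS26 by 0.49 and CESA6 by 1.16, and of these only CESA6 kept its call. Without base replicate 1 LTP110-B, BGLU30 and FOR1 differed by 12.17, 11.98 and 10.76, KIN14F by 6.69, RPS26 by 2.15 and CESA6 by 4.71. On log2(signal + 16) BGLU30 rose by 5.10 and KIN14B by 2.85. Cytosolic ribosomal proteins rose at 5 of 21 (RPS26 1.32 ± 0.30; adjusted p = 2.68e-05, and adjusted p = 0.38 with an estimated correlation). Without base replicate 2 the call was lost for KIN14F (adjusted p = 0.495), KIN14B (adjusted p = 0.133), LTP110-B (adjusted p = 0.0757), BGLU30 (adjusted p = 0.0967), the peroxidase gene (adjusted p = 0.0876), FOR1 (adjusted p = 0.401) and RPS26 (adjusted p = 0.24), and without top replicate 1 for KIN14F (adjusted p = 0.0806).

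Of 13 diterpenoid phytoalexin synthesis enzymes 7 fell (CPS4 -5.51 ± 1.16, or -2.40 on log2(signal + 16), CYP99A2 -4.03 ± 1.17, or -2.61 without base replicate 2; adjusted p = 0.00365, and adjusted p = 0.38 with an estimated correlation), and of 10 chitinases 7 fell (Cht8 -5.33 ± 0.98, Cht6 -3.05 ± 0.95; adjusted p = 0.0165, and adjusted p = 0.38 with an estimated correlation). Of 23 photosynthetic genes 1 rose and 11 fell (LFNR1 -2.42 ± 0.26, ndhM -2.35 ± 0.28; adjusted p = 1.03e-05, and adjusted p = 0.38 with an estimated correlation). ASMT fell by 8.08, the potassium transporter HAK16 dropped by 5.66 and PIP2-7 decreased by 5.50. The starch and sugar genes GBSSI (-1.30 ± 0.62, adjusted p = 0.125), SUT1 (0.02 ± 0.40, adjusted p = 0.984) and BEI (0.65 ± 0.23, adjusted p = 0.0342) were not called, and their values rest on which base array is used. Without base replicate 1 GBSSI differed by -2.05 and passed (adjusted p = 0.0381), BEI by -0.01 and SUT1 by -0.53. Without base replicate 2 BEI differed by 1.31 and passed (adjusted p = 5.03e-05), GBSSI by -0.54 and SUT1 by 0.56. Limma called 3303 probe sets higher and 3486 lower at the base (5231 and 5638 without the 2-fold limit), 3794 and 3331 with array medians set equal and 3124 and 4218 on the deposited scale, so which direction had more calls depended on the scaling. Without base replicate 2 the counts were 1209 and 1628, and without base replicate 1 4573 and 5306, each lone array being assumed to vary like the other groups. A fit of the 5 sheath arrays alone called 347 and 774, and array weights 1675 and 1950. Array weights ended the call of KIN14F (adjusted p = 0.139), KIN14B (adjusted p = 0.118), CYP99A2 (adjusted p = 0.136) and Cht6 (adjusted p = 0.217). Of the 28 called genes named for the sheath, 16 were not called in the fit of the 5 arrays. Without base replicate 2 the call was lost for CYP99A2 (adjusted p = 0.291) and Cht6 (adjusted p = 0.184), and without top replicate 2 for CYP99A2 (adjusted p = 0.05).

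**Figure D2:**
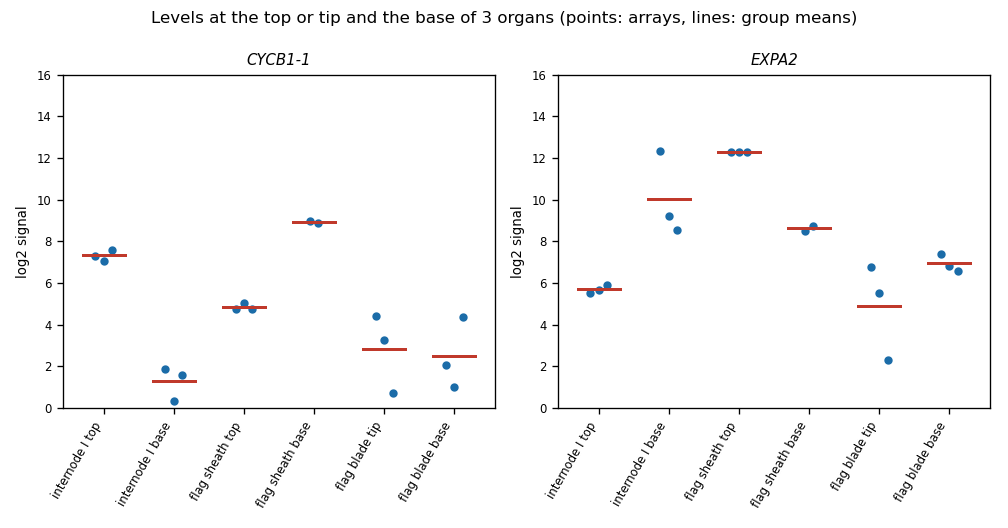
Log2 level of CYCB1-1 and EXPA2 on each array at the top (or tip) and base of internode I, the flag sheath and the flag blade after quantile normalization; points are arrays and short lines are group means. CYCB1-1, a cyclin, differs by -6.05 (base minus top) in the internode and 4.08 in the sheath, and EXPA2 by 4.33 and -3.69.

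The flag leaf blade (9 arrays of its tip, middle and base) was compared with the flag leaf sheath (5 arrays). The sheath was higher in genes of wall synthesis, and the blade in genes of photosynthesis. The expansin EXPB2 was 105-fold higher in the sheath (blade minus sheath -6.71 ± 0.68, adjusted p = 3.39e-08) and ZIP3 206-fold (-7.69 ± 0.34, adjusted p = 3.95e-13). In the blade the (p)ppGpp synthase CRSH2 was 32.6-fold higher (5.03 ± 0.40, adjusted p = 1.13e-09) and the chloroplast protease FTSH6 31.7-fold (4.99 ± 0.44). On log2(signal + 16) blade minus sheath was -5.86 for EXPB2, -5.50 for ZIP3 and 4.01 for FTSH6. Without both sheath base arrays CRSH2 was higher by 2.54 and FTSH6 by 3.12.

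Of 23 photosynthetic genes 13 rose and 1 fell in the blade (ndhM 3.04 ± 0.18, LFNR1 1.95 ± 0.16; adjusted p = 4.62e-07, and adjusted p = 0.394 with an estimated correlation), the lower one being PORA (-3.29 ± 0.23). Of 8 chlorophyll synthesis genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; CHLI 2.05 ± 0.60; adjusted p = 0.00884, and adjusted p = 0.394 with an estimated correlation). With the mean of all probe sets of a gene that list had an adjusted p of 0.0995. PDX12 rose by 5.28 ± 0.52, the potassium transporter HAK16 by 4.05 ± 0.45 and the tonoplast aquaporin TIP1-2 by 3.65 ± 0.63. Without both sheath base arrays ndhM was higher by 1.87 and PDX12 by 2.82, HAK16 differed by 1.22 and TIP1-2 by 1.26, and the call was lost for LFNR1 (0.73), CHLI (adjusted p = 0.148), HAK16 (adjusted p = 0.0841) and TIP1-2 (adjusted p = 0.257), and without base replicate 2 alone for CHLI (adjusted p = 0.0771). Array weights ended the call of CHLI (adjusted p = 0.118).

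All 6 genes of secondary wall cellulose and lignin synthesis were lower in the blade (6 adjusted over the list alone; CESA4 -3.95 ± 0.47; adjusted p = 0.00942, and adjusted p = 0.267 with an estimated correlation), as were all 5 primary wall cellulose synthases (5 adjusted over the list alone; CESA8 -3.51 ± 0.21; adjusted p = 0.00127, and adjusted p = 0.394 with an estimated correlation). Of 15 xylan proteins 8 fell (IRX9 -4.34 ± 0.42; adjusted p = 0.00127, and adjusted p = 0.394 with an estimated correlation), of 9 tubulins 8 (TUBB1 -3.55 ± 0.21; adjusted p = 0.000597, and adjusted p = 0.394 with an estimated correlation), and of 32 kinesins 17 with 2 higher (KIN7K -3.35 ± 0.23; adjusted p = 0.00407, and adjusted p = 0.394 with an estimated correlation). Of 24 Aux/IAA auxin response repressors 13 were lower in the blade and 2 higher (IAA30 -4.72 ± 0.32, IAA14 -4.19 ± 0.59; adjusted p = 0.00722, and adjusted p = 0.394 with an estimated correlation). Of 25 expansins 13 fell and 0 rose, with EXPB3 at -5.39 ± 0.52, while the list test did not pass (adjusted p = 0.0664). Of 26 mineral element transporters 5 rose and 10 fell in the blade (5 and 10 adjusted over the list alone), with NRAMP5 at -4.50 ± 0.48, ZIP5 at -4.01 ± 0.31 and Lsi6 at -2.55 ± 0.26 (list adjusted p = 0.391). The salt-induced lectin SALT fell by 7.21, NH5 dropped by 9.04 and BURP17 decreased by 6.57. Without both sheath base arrays the difference was -1.86 for CESA4, -2.26 for CESA8, -2.15 for KIN7K, -2.27 for IAA14 and -1.84 for ZIP5, still calls, and -0.99 for TUBB1, under the 2-fold limit. IAA14 differed by -2.70 on log2(signal + 16).

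Limma called 4137 probe sets higher and 4292 lower in the blade (8379 and 8498 without the 2-fold limit). With the hybridization controls set equal, under which the median of all probe sets moved from 0.02 to -0.24, the counts were 2923 and 6160. On the deposited scale they were 4500 and 4302, with more probe sets higher than lower. Without both sheath base arrays, an alternative added after seeing the data, 1597 were higher and 2257 lower, and the call was lost for 5 of the 25 called genes named.

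**Figure D3:**
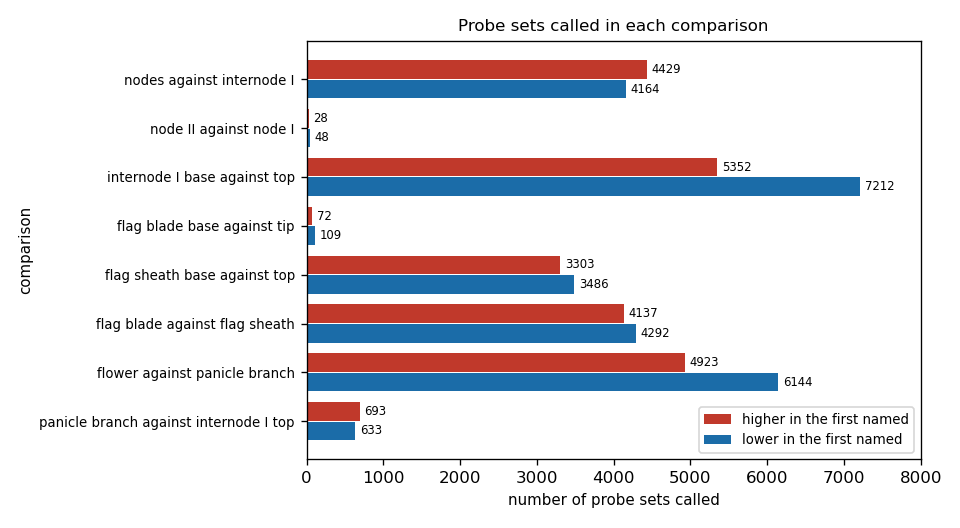
Number of probe sets called higher and lower by limma in each of the 8 comparisons (bars from 0, out of 38647 tested). Internode I base against top has the most calls (5352 and 7212), and node II against node I the fewest (28 and 48).

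The flower, sampled before anthesis, was compared with the panicle branch that bears it (3 arrays each). Actin 3' minus 5', a sign of RNA quality, averaged 0.89 in flower and 1.66 in panicle branch, and the same measure on ubiquitin -0.86 and -0.72. The MADS-box genes MADS2 and MADS16 were 14.8-fold and 7.29-fold higher (3.89 ± 0.76 and 2.87 ± 0.32; adjusted p = 0.000219 and 2.2e-07), with all 3 flower arrays above every panicle branch array. The chitinase Cht7 was 1292-fold higher (10.34 ± 0.97, adjusted p = 1.39e-08), the actin-depolymerizing factor ADF-6 1244-fold (10.28 ± 0.92), the expansin EXPB10 971-fold (9.92 ± 1.15) and the sugar transporter MST5 874-fold (9.77 ± 1.06). These 4 rose by 9.56, 8.43, 9.31 and 7.23 on log2(signal + 16). The panicle branch was higher in genes of the chloroplast, such as ALDP (flower minus branch -7.91 ± 0.91, adjusted p = 2.64e-07).

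Of 17 floral MADS-box regulators 12 rose and 3 fell (12 and 3 adjusted over the list alone), with MADS7 at 7.90 ± 0.87, MADS58 at 7.68 ± 0.72 and MADS17 at 7.14 ± 0.98 (adjusted p = 0.00602, and adjusted p = 0.251 with an estimated correlation). Of 25 expansins 16 rose and 3 fell (EXPA26 9.61 ± 0.56, EXPA32 8.08 ± 1.32; adjusted p = 0.00702, and adjusted p = 0.399 with an estimated correlation). All 5 lipid transfer proteins rose (LTP110-B 6.22 ± 1.37; adjusted p = 0.0375, and adjusted p = 0.251 with an estimated correlation), as did 6 of 9 tubulins (TUBB8 5.60 ± 0.53; adjusted p = 0.00746, and adjusted p = 0.416 with an estimated correlation) and 4 of 5 primary wall cellulose synthases (4 adjusted over the list alone; CESA5 2.73 ± 0.67; adjusted p = 0.0269, and adjusted p = 0.416 with an estimated correlation). Transporters moved both ways: of 22 HAK potassium transporters 7 rose and 3 fell (HAK26 8.67 ± 0.91, or 5.07 on log2(signal + 16), HAK4 -5.16 ± 0.99), and of 22 YSL and ZIP metal transporters 7 rose and 4 fell (YSL4 9.11 ± 1.33, YSL13 -6.24 ± 0.59), with neither list called (adjusted p = 0.206 and 0.74). The gibberellin synthesis gene KAO rose by 6.08 ± 0.38 and GA20ox2 fell by 2.91.

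Photosynthetic transcripts were lower in the flower: 17 of 23 nuclear genes fell (ndhM -2.61 ± 0.25, list adjusted p = 2.11e-06, and adjusted p = 0.399 with an estimated correlation). So did 7 of 8 genes in the chlorophyll synthesis list (7 adjusted over the list alone, adjusted p = 0.00127, and adjusted p = 0.251 with an estimated correlation). Among them were the transcription factor GLK1 (-2.73 ± 0.28) and CAO1 (-2.13 ± 0.19). MYBAS1 fell by 8.57, the auxin transporter PIN4 dropped by 7.02, PIP2-7 decreased by 6.98 and BURP2 fell by 6.68. Limma called 4923 probe sets higher and 6144 lower in the flower (6680 and 9879 without the 2-fold limit). Which direction had more calls depends on the scaling: 5120 were higher and 4993 lower on the deposited scale, and 5130 and 4521 with the hybridization controls set equal. The median of all probe sets was -0.18, and -0.28 to -0.02 under the other scalings, a shift smaller than the changes named here.

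The panicle branch and the top of internode I had similar profiles (r = 0.904 across probe sets on average). Of the floral MADS-box genes MADS5 was 515-fold higher in the branch (9.01 ± 1.19, adjusted p = 5.58e-05) and MADS1 54.6-fold (5.77 ± 0.60, adjusted p = 2.65e-06). MADS5 rose by 5.51 and MADS1 by 5.06 on log2(signal + 16). BURP2 (9.19 ± 1.43), the ethylene synthesis gene ACO1 (6.91 ± 1.43) and OSE727A (5.48 ± 1.28) rose as well. The internode top was higher in the tubulin TUBB8 (branch minus internode -4.55 ± 0.53, adjusted p = 1.02e-05) and in the MADS-box genes MADS22 (-3.67 ± 0.23) and MADS55 (-3.62 ± 0.26).

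Of 17 floral MADS-box regulators 2 rose (6 adjusted over the list alone; adjusted p = 0.0142, and adjusted p = 0.294 with an estimated correlation). Among homeobox genes hox14 (5.61 ± 0.72), OSH43 (3.41 ± 0.84) and OSH6 (3.12 ± 0.71) rose, and among mineral element transporters 3 rose and 2 fell of 26 (3 and 3 adjusted over the list alone; ZIP3 4.64 ± 0.49, IRT1 4.35 ± 0.39; list adjusted p = 0.576). On the log2(signal + 16) scale hox14 rose by 2.58, OSH43 by 2.15 and ZIP3 by 2.62. The auxin-conjugating enzyme GH3.2 rose by 4.65 ± 0.56, and the metallothionein MT1B by 3.63 ± 0.59. Of 9 tubulins 3 fell (TUBB6 -2.20 ± 0.57; adjusted p = 0.00249, and adjusted p = 0.35 with an estimated correlation), and of 5 primary wall cellulose synthases 3 (3 adjusted over the list alone; CESA3 -1.48 ± 0.16; adjusted p = 0.00327, and adjusted p = 0.294 with an estimated correlation). The kinesin KIN14O fell by 2.54 and ASMT3 dropped by 2.63. Limma called 693 probe sets higher and 633 lower (842 and 961 without the 2-fold limit), and with the hybridization controls set equal, which moved the median of all probe sets from -0.02 to 0.18, 763 and 286. With array medians set equal the lower calls were the more numerous, 517 higher and 653 lower. A fit of these 6 arrays alone called 207 and 185, and 8 of the 19 called genes named lost their call. ASMT3 lost its call without any 1 of the 6 arrays, with no filter (adjusted p = 0.0784), with array weights (0.0502) and with the hybridization controls set equal (0.0726). Calls lost without panicle branch replicate 1 were TUBB6 (adjusted p = 0.0605) and ASMT3 (adjusted p = 0.0682). Those lost without branch replicate 2 were TUBB6 (adjusted p = 0.136) and ASMT3 (adjusted p = 0.221), and without branch replicate 3 OSE727A (adjusted p = 0.0527), OSH43 (adjusted p = 0.074) and ASMT3 (adjusted p = 0.0573). Without internode top replicate 1 they were ASMT3 (adjusted p = 0.101). Without top replicate 2 they were OSH43 (adjusted p = 0.118), OSH6 (adjusted p = 0.0577), TUBB6 (adjusted p = 0.0764) and ASMT3 (adjusted p = 0.148), and without top replicate 3 OSE727A (adjusted p = 0.096), TUBB6 (adjusted p = 0.1) and ASMT3 (adjusted p = 0.104).

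A probe set was taken as preferring an organ when every contrast with the other 6 organs was called upward. The level of an organ is the mean over its sampled parts, so a part of another organ can lie closer than the margin shows. Flower had 1772 such probe sets, flag blade 1166, internode I 307, panicle branch 169 and flag sheath 80. Among those of the flower were the chitinase Cht7 (log2 mean 15.32, against 4.99 in the next organ), EXPB10 (14.87 against 4.95), CML28 (11.89 against 3.28), and the actin-depolymerizing factors ADF-9 (14.01 against 5.02) and ADF-1 (14.27 against 5.64). Of 17 floral MADS-box regulators 12 preferred the flower. In the flag blade HAK16 stood 10.9-fold over the next organ, LOX8 10.6-fold, EIL1 9.9-fold, FTSH6 8.97-fold and NAAT1, an enzyme of mugineic acid synthesis, 8.7-fold. The margin of HAK16 depends on the sheath base arrays: it averaged 12.19 in the blade, 10.96 at the sheath top and 5.31 at the sheath base. GST1 (4.57-fold), OsCASPL5B1 (4.35-fold), KIN14A (4-fold), NEK4 (3.6-fold) and AtMAP70-4 (3.47-fold) led the internode genes. Those of the panicle branch were led by BURP2 (103-fold), LAC7 (6.07-fold), the cytokinin oxidase CKX4 (4.22-fold), ALDP (4-fold) and MADS50 (3.49-fold), and those of the sheath with a name by OsCASPL2C1 (2.76-fold) and SPL2 (2.46-fold). ALDP averaged 13.60 in the branch and 12.31 at the top of internode I, closer than its margin. As LAC7 fell from the internode top to its base, its internode mean of 10.23 hides a higher top. Both nodes together exceeded the 5 other organs at 323 probe sets, among them Lsi2 (12.30 against 3.64 in the next organ), WOX11 (10.20 against 5.12), LA, a gene of shoot gravitropism (10.6-fold), CSLA9 (6.53-fold) and PSK5 (6.19-fold). For the flower genes named here and for Lsi2 and WOX11 the next organ's mean lies below 5.83, so no fold is given. Also among the probe sets of both nodes, 6 of 26 mineral element transporters were found. ZIP3 was among the node genes although the sheath base arrays read 12.62 and 12.08, against 12.31 to 13.26 in node II. The sheath mean also holds the sheath top, where ZIP3 was lower.

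With the hybridization controls set equal the counts were 95 for panicle branch, 137 for internode I, 312 for flag sheath and 185 for both nodes; without both sheath base arrays flag blade had 418 and flag sheath 183. Single nodes had few: 2 probe sets for node I, 1 of them GH3.11 (2.87-fold over the next organ), and 5 for node II, none with a named gene. Node I had 0 without its replicate 1 or 3, and 1 without panicle branch replicate 2, node II replicate 2 or node II replicate 3. Node II had 13 without its replicate 1, 1 without its replicate 2 or 3, and 1, 3 and 0 without node I replicate 1, 2 and 3. It had 2 without flower replicate 1 and 3 without sheath top replicate 1.

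The whole blades of the flag leaf, leaf 2 and leaf 4 had 1 array each, so their differences have no replicate check and no test. Their hybridization controls averaged 11.47, 11.27 and 10.53. The leaf 4 array thus lay further from the other blades than replicates of any group from each other (at most 0.57). From flag leaf to leaf 4 the chlorophyll breakdown gene SGR was 13.9-fold higher. On the log2 scale MS was higher by 4.88, the metallothionein MT1B by 4.56, the lipoxygenase LOX8 by 3.92 and the nicotianamine synthase NAS3 by 3.67. Pi21 differed by -7.32, the chitinases Cht5 and Cht4 by -6.30 and -5.93, the tubulin TUBB6 by -5.07 and the expansin EXPB3 by -5.06. On log2(signal + 16) Pi21, Cht5 and Cht4 differed by -5.24, -5.34 and -4.56. In leaf 2 minus flag leaf, SGR was 0.90, NAS3 3.97 and Pi21 -1.44. The median of 23 photosynthetic genes was -0.89 and that of 10 chitinases -2.57 in leaf 4 minus flag leaf, each at percentile 0 among 10000 random lists of the same size matched on level, which describes these arrays and is not a test of a difference between leaves. The 8 chlorophyll synthesis genes had a median of -0.95 (percentile 0.01). Among lists that were higher in leaf 4, 8 dehydration and heat response genes had a median of 0.72 and 9 GH3 enzymes one of 1.35. Of 5 genes of chlorophyll breakdown and leaf senescence 1 was at least 2-fold higher (median 0.40). Among bright probe sets 723 were at least 2-fold higher and 839 lower in leaf 4 than in the flag leaf, and pairs of replicate arrays of the blade parts differed that much at 301 to 1659.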

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

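Tests chosen only after the result was seen were those of a wrong label for a sheath base array, of node tissue as the source of its raised probe sets and of fungal RNA; for the other tests on the sheath base arrays, the condition that a value must exceed its spread was added after the result was seen, and the division test, written for 3 gene lists, was first run on 1 of them and corrected once that result had been seen. The genes named in this part for opposite changes were picked after their values were seen, and so were their values on log2(signal + 16) and with 1 array left out.

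Base minus top was compared between organs in 1 model by testing the difference of the differences. Between internode I and the flag sheath 323 probe sets were called in opposite directions with a called difference, 428 without sheath base replicate 1 and 243 without replicate 2. Among them were CYCB1-1 (-6.05 ± 0.75 against 4.08 ± 0.84, difference -10.13, adjusted p = 7.19e-07), EXPA2 (4.33 ± 0.84 against -3.69 ± 0.94, difference 8.02, adjusted p = 5.59e-05), EXPB3 (4.21 ± 0.75 against -2.44 ± 0.83, difference 6.65, adjusted p = 0.000122) and COPT1 (3.93 ± 0.60 against -2.69 ± 0.67, difference 6.61, adjusted p = 9.8e-06). CYCB1-1 is a mitotic cyclin, EXPA2 and EXPB3 are expansins and COPT1 is a copper transporter; the sheath base arrays of CYCB1-1 read 8.98 and 8.90, and those of EXPA2 8.48 and 8.76. For EXPB3 they read 10.23 and 13.10, against a sheath top mean of 14.11, and for COPT1 7.13 and 10.47, against 11.49, so most of both decreases comes from replicate 1. Without it the sheath difference was -1.01 (adjusted p = 0.475) for EXPB3 and -1.02 (adjusted p = 0.248) for COPT1, no longer calls, and that of EXPB3 was also lost when any 1 of the 3 sheath top arrays was left out (adjusted p up to 0.0701). The internode base mean of CYCB1-1 is near the floor, and on log2(signal + 16) its changes were -3.24 and 3.49, with a difference of -6.72.

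Between internode I and the flag blade 43 probe sets changed in opposite directions, with Pir7b (2.60 ± 0.35 against -2.20 ± 0.35, difference 4.79, adjusted p = 1.83e-07), PSK5 (2.30 ± 0.43 against -2.16 ± 0.43, difference 4.46, adjusted p = 5.19e-06), CYP71P1 (2.04 ± 0.45 against -2.39 ± 0.45, difference 4.42, adjusted p = 9.62e-06) and MT2C (-2.05 ± 0.47 against 2.17 ± 0.47, difference -4.21, adjusted p = 3.11e-05), here at another probe set of MT2C than in the comparison of blade base and tip. Between sheath and blade there were 24, with PSK5 (2.30 ± 0.48 against -2.16 ± 0.43, difference 4.46, adjusted p = 7.43e-05), BZIP60 (1.40 ± 0.35 against -1.67 ± 0.31, difference 3.07, adjusted p = 0.000112), ZIP1 (1.67 ± 0.27 against -1.06 ± 0.24, difference 2.72, adjusted p = 3.43e-05) and OsPK2 (1.67 ± 0.23 against -1.03 ± 0.20, difference 2.70, adjusted p = 6.77e-06). The tested differences of these genes and of those above were called on log2(signal + 16) and with any 1 of the 17 arrays of the compared parts left out. The calls within an organ were less firm. The sheath changes of PSK5 (1.32, adjusted p = 0.108) and BZIP60 (0.80, adjusted p = 0.219) were not called without sheath base replicate 2. The blade change was not called for PSK5 without tip replicate 2 or base replicate 2 (adjusted p up to 0.0825), for CYP71P1 without base replicate 2 (0.067), for OsPK2 without tip replicate 3 or base replicate 2 (up to 0.0968) and for MT2C without tip replicate 2 or 3 or base replicate 2 or 3 (up to 0.191, where it was 1.43). That of ZIP1 was not called in 11 of the fits with 1 array left out (adjusted p up to 0.167), nor on log2(signal + 16) (-0.77). On simulated data for internode I against sheath, 111 of 200 differences of 3 log2 units were recovered with 13 false calls among 38647 probe sets. These data gave all groups the same SD of a probe set, unlike the real sheath base arrays.

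A control probe set for the EF1 alpha gene of the rice blast fungus, outside the rice probe sets tested, was 5.72 log2 units higher on the 3 flower arrays (8.11 to 9.00) than on the other 32 (highest 6.24), on the deposited scale. If fungal RNA were the source, other fungal probe sets would be raised too. The 9 others differed by a median of 1.12 (-0.50 to 2.98), which exceeds that of dim rice probe sets (0.46, quartiles -0.22 to 1.19) by 0.665, inside that spread, so this stays open. Among the 9, those for the same EF1 alpha gene differed by 0.14, 1.12 and 2.19. Their flower means (4.07, 4.92 and 4.70) lay below the highest other array (6.20, 6.27 and 6.24). Cross-hybridization of a rice transcript high in flower also stays open. Among rice probe sets named as elongation factor 1 alpha the highest flower difference was 0.316, but another transcript could match, and probe sequences were not used here. Of all rice probe sets 679 were raised as much in flower.

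The 2 flag sheath base arrays correlated at r = 0.864, where every other replicate pair had 0.917 or more, and read 1.98 and 1.12 for actin 3' minus 5' (a gap of 0.86, at most 0.74 within another group) and 11.12 and 10.59 for the hybridization controls (a gap of 0.53, at most 0.57 elsewhere). Ubiquitin 3' minus 5' read -0.67 and -0.58 on these arrays. Replicate 2 being an array of another sampled organ is argued against by its mean correlation with the nearest group, node II (0.878), minus the lowest correlation within node II (0.939), of -0.0606, and more dividing tissue in it by a median of -0.157 for replicate 2 minus replicate 1 over 32 division genes (quartiles -0.52 to 0.26), where a median above 1 was predicted. Node tissue as the source of the 2983 probe sets more than 4-fold higher in replicate 2 is argued against by 15 others, picked without the sheath base arrays. These were at least 3 log2 units higher in both nodes than in all other groups but the sheath base. In replicate 2 they lay at a median of -4.24 from the lower node (quartiles -4.93 to -3.20), Lsi2 at 3.02 against 12.43 in node I. Some unnamed ones went the other way: in replicate 2, replicate 1 and node I a probe set read 14.32, 9.85 and 14.17, and another 8.09, 5.26 and 8.91. Of the 2983, 82.1% exceeded both nodes in replicate 2, but they were picked for being high there, so no conclusion is drawn from that share. Of a smaller share of node tissue nothing was learned from 438 probe sets at least 3 log2 units higher in internode base than in nodes, sheath top and replicate 1, which replicate 2 exceeded by a median of 1.15 (quartiles -0.28 to 2.41), since they were picked for being low in replicate 1. Such a share stays open, as do a difference in RNA quality or labelling, which the control values leave undecided, and one in position along the sheath, which was not tested.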

How the results depend on the processing

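Chosen after seeing the data were the scaling on hybridization controls and leaving out both sheath base arrays. Counts of called probe sets stayed within 1.5 times the main count under the settings tried, with the exceptions that follow; the strict filter tests fewer probe sets and the compared arrays alone hold fewer arrays by construction, and for the others the cause was not tested. Genes named in the comparisons kept their direction wherever they were called, and of 1579 values with 1 array left out 60 lost the call and 4 gained it. The fit of the compared arrays alone lost 42 of 199 and array weights 6. With log2(signal + 16) 0 of 199 lost the call, and 3 of 10 whole-blade genes moved by more than their residual SD. Of 67 list tests given, 48 lost their call with an estimated correlation.

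With a filter at the 75th percentile they were nodes higher 2538 (from 4429), nodes lower 2628 (from 4164), blade over sheath higher 2728 (from 4137), flower higher 3225 (from 4923). With the deposited scale they were node II higher 49 (from 28). With log2(signal + 16) they were node II higher 72 (from 28), node II lower 73 (from 48), node I preferring 7 (from 2), node II preferring 19 (from 5). With no filter they were node II higher 18 (from 28), node II lower 31 (from 48), blade base higher 45 (from 72), node II preferring 3 (from 5). With a trend in the prior variance they were node II higher 44 (from 28), node II preferring 8 (from 5). With possibly cross-hybridizing probe sets left out they were node II higher 17 (from 28), node II lower 27 (from 48), node I preferring 1 (from 2). With array weights they were node II higher 166 (from 28), node II lower 212 (from 48), blade base higher 308 (from 72), blade base lower 294 (from 109), sheath base higher 1675 (from 3303), sheath base lower 1950 (from 3486), node I preferring 25 (from 2), node II preferring 14 (from 5). With the compared arrays alone they were node II higher 0 (from 28), node II lower 0 (from 48), blade base higher 0 (from 72), blade base lower 2 (from 109), sheath base higher 347 (from 3303), sheath base lower 774 (from 3486), panicle branch higher 207 (from 693), panicle branch lower 185 (from 633). With array medians set equal they were node II lower 96 (from 48), panicle branch preferring 88 (from 169), node I preferring 4 (from 2), flag sheath preferring 152 (from 80), leaf 2 minus flag leaf, higher 920 (from 448), leaf 4 minus leaf 2, lower 988 (from 581). With the hybridization controls set equal they were blade base higher 37 (from 72), panicle branch lower 286 (from 633), panicle branch preferring 95 (from 169), internode I preferring 137 (from 307), node I preferring 0 (from 2), node II preferring 2 (from 5), flag sheath preferring 312 (from 80), both nodes preferring 185 (from 323). With both sheath base arrays left out they were blade over sheath higher 1597 (from 4137), blade over sheath lower 2257 (from 4292), flag blade preferring 418 (from 1166), flag sheath preferring 183 (from 80). With an estimated correlation they were gene lists: list tests called 2 (from 73).

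With 1 array left out the ranges were node II higher 10 to 51, node II lower 13 to 67, blade base higher 26 to 116, blade base lower 69 to 123, sheath base higher 1209 to 4573, sheath base lower 1628 to 5306, node I preferring 0 to 3, node II preferring 0 to 13. For the sheath base the lone array left is assumed to vary like the other groups. The replicate numbers were not taken as pairs: of 44 same-numbered pairs across compared groups 0 had a correlation of deviations over 0.1 (-0.106 to 0.0595). With the replicate number as a block the counts were nodes 4434 higher and 4143 lower, node II 37 higher and 47 lower, internode base 5352 higher and 7227 lower, blade base 78 higher and 111 lower, sheath base 3353 higher and 3527 lower, blade over sheath 4191 higher and 4309 lower, flower 4895 higher and 6133 lower, panicle branch 694 higher and 633 lower. The block ended the call of ASMT3 in panicle branch against internode top (adjusted p = 0.0611) and changed no other of the 199 values tried for genes named in the comparisons. It was not tried on the opposite changes, and organ-preferring genes were counted but not followed by name.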

Other observations

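The test of shared changes from top to base in internode I and flag sheath was chosen only after the result was seen; the other tests in this part were written before their results were seen.

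Further gene lists were counted in these comparisons, and most of them did not pass as lists. Of 15 xylan synthesis and acetylation proteins 2 rose and 5 fell in the nodes against internode I, with IRX9 at 3.09 ± 0.43 and XOAT2 at -1.70 ± 0.15. The list was lower (adjusted p = 0.0281, and adjusted p = 0.572 with an estimated correlation), and had an adjusted p of 0.0654 with the mean of all probe sets of a gene. Of 9 growth-regulating factors 5 rose in the nodes (GRF10 2.34 ± 0.50; list adjusted p = 0.158), and of 11 SWEET sugar transporters 2 rose and 5 fell (SWEET11 4.34 ± 0.68, SWEET1B -3.81 ± 0.59; list adjusted p = 0.357). In the flower 5 rose and 4 fell of the same 11 against panicle branch, with SWEET5 at 5.94 ± 0.88 and SWEET1B at -4.94 ± 0.84 (list adjusted p = 0.901).

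At the internode base 8 rose and 4 fell of 26 mineral element transporters (8 and 4 adjusted over the list alone), with IRT1 at 4.39 ± 0.39 and Lsi1 at -4.15 ± 0.42 (list adjusted p = 0.453). Of 25 expansins 10 rose and 3 fell (EXPB11 5.30 ± 0.71; list adjusted p = 0.297). At the sheath base 1 rose and 7 fell of 20 genes of ammonium and nitrate uptake and assimilation, with AMT1-3 at -3.12 ± 0.36 and GLN2 at -2.35 ± 0.22 (adjusted p = 0.0472, and adjusted p = 0.38 with an estimated correlation). That list had an adjusted p of 0.0633 on the deposited scale and 0.0734 with the mean of all probe sets of a gene. Of 8 clock and photoperiod genes 2 fell (2 adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.38 with an estimated correlation), and the list had an adjusted p of 0.0633 on the deposited scale and 0.07 with array medians set equal. PRR37 was at -1.24 ± 0.24, and at -0.96 without base replicate 2, under the 2-fold limit.

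A hypothesis is that the same probe sets change from top to base in internode I and in the flag sheath. Across probe sets, which are not independent replicates, base minus top in the organs correlated at r = 0.476, and at 0.255 and 0.537 with sheath base replicate 1 or 2 alone. The organs share no arrays. Higher at the base in both were 1803 probe sets, where independent lists would share 457, and lower in both 2025 against 651. A gradient that both organs share would give such an overlap, with the 323 opposite probe sets as exceptions, but the overlap does not single out that source. Replicate 2, which gave the closer match, also correlated more with the internode base arrays (0.844) than replicate 1 did (0.786). Whether the sheath base samples held internode tissue was not tested.

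Few probe sets differed between blade base and tip. A larger spread between blade arrays is argued against, since the ratio of median probe set SDs of blade to internode was 0.991. The median size of a base minus top difference was 0.26 in the blade and 0.84 in the internode, and whether a gradient of another kind exists along the blade was not tested.

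Other splits of the same arrays into groups of the same sizes were counted. For nodes against internode I, flag blade against sheath and organ-preferring probe sets, only 1 of 100 splits, the real one, gave as many calls (8593, 8429 and 3824, against at most 3730, 6471 and 26). A share of 0.01 is the lowest that 100 splits can give. Other splits, here and below, mix organs or parts within a group, which raises the spread used by the test and so favours fewer calls. The counts therefore cannot exclude chance. Which arrays form the splits that call 3730 and 6471 probe sets was not examined, and the cause of these counts was not tested. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 with as many calls in each, and the real and the highest other counts were 76 and 43 for node II against node I, and 12564 and 18 for internode base against top. They were 181 and 32 for blade base against tip, 11067 and 11 for flower against panicle branch, and 1326 and 10 for panicle branch against internode top.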
